A study of Chryseobacterium sp. with 6 samples.

How the data were processed

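Total RNA of strain WX1 was extracted with TRIzol and treated with DNase I, and libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. There were 3 control libraries and 3 libraries from cultures with 50 mg/L doxycycline. Per the submitters' processing notes, the tools were Bowtie2, RSEM and DESeq2, with no versions or options. The genome build, the annotation, the strandedness of counting and any filter are not given in the sources used here.

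One table of 5194 features was deposited, with 6 columns that hold TPM per library. The unit is read from the values, since each column sums to 1000000, and the authors' TPM were used as deposited. Its 2 mean columns hold the authors' mean TPM per group and were not used. The table also holds, per the file headers, a fold change (ratio), a log2 fold change, a p-value and an adjusted p-value of doxycycline over control. These come from the authors' own comparison and are quoted only where the authors' deposited table is named. A gene name is given for 1571 features. TPM divides by feature length and keeps no depth, so no counting interval or floor is given, and the depth behind each value is unknown. A value of 0 can be a failed estimate for a short feature, so features listed at 0 are described by each library's value. How reads of similar gene copies and of overlapping or antisense features were assigned is unknown without the counting options.

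The design fixed before the data were examined named a count test and, for a table of TPM only, limma-trend. The table holds no counts, so the second branch was used. Features with at least 1 TPM in at least 3 libraries (4955 features) were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with group as the term, a mean-variance trend, robust empirical Bayes and Benjamini-Hochberg adjustment (threshold 0.05). Fold changes on this scale understate those of low genes. The same fit was run after division of TPM by median-of-ratios factors (RLE, relative log expression), computed over the tested features above 0 in all libraries. These factors were 0.877, 0.483 and 0.814 for control replicates 1 to 3 and 1.20, 1.48 and 1.64 for doxycycline replicates 1 to 3. Values from that fit are called relative to the typical gene. That fit was planned as an alternative scaling. It was made the leading scale after the data were seen, because the TPM scale moves the median gene by 0.89. In the pair correlations of log2(TPM + 1), no 2 libraries of a group held identical values for more than 0.464% of features, and all 6 were kept as separate samples.

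Gene lists were written as patterns in gene names and descriptions before the data were examined. Of 20 lists, 3 were corrected from gene names alone, but after the data and the counts of these lists had been seen. The gliding list had matched the word transport, the synthetase list 6 other enzymes such as argG and metX, and the translation factor list the transcription factor GreA and a methyltransferase. The list for ribosomal and transfer RNA matched a tRNA-binding protein and no RNA row, so it was left out and no such rows were removed. Lists were tested with camera (correlation 0.01, trended variance), and with fry and an estimated correlation as alternatives, over the 18 lists with at least 5 tested members. Named genes follow a rule fixed beforehand. It takes the 5 largest rises and 5 largest falls past the TPM threshold with no overlap between groups, a mean of at least 10 TPM in the higher group and a name or informative description. It adds the member of each list with the largest rise and that with the largest fall, or 2 of one direction, and all members of the tetracycline resistance list. The rule gave 46 features.

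Alternatives were other scalings, pseudocounts of 0.1 and 5, no filter, a filter of 10 TPM, an adjusted p under 0.01, a minimum absolute log2 change of 1, the replicate number as a block, and each library left out. The scripts were tested on simulated data for the comparison of doxycycline with control. Values were drawn for 4948 features from the real means and residual spreads, and 200 genes were changed. A first run failed, because features with values of 0 in some libraries had spreads so large that they set each simulated total. The spread of features of at least 10000 TPM was then set to the median. The pass rule was changed after these runs from a share of recovered genes to the size of the estimates, so the low shares below are given as they are. On the TPM scale, 14% of genes changed by 1 on the log2 scale and 64% of those changed by 2 were called, with median estimates of 1.03 and 1.99. Relative to the typical gene these shares were 18% and 66%, and 0.0211% of unchanged genes were called on either scale. When one simulated feature took 50% of the treated TPM (4932 features), 62.7% of unchanged genes were called on the TPM scale and 0.0423% on the relative scale. In a camera simulation over 4947 features a list of 40 genes raised by 1 was called, as were 3.5% of random lists. Noise was drawn independently for each gene there, whereas estimated correlations within the 18 real lists were 0.23 to 0.64. That share is therefore not the rate of false calls by camera in these data.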

Results

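Transcript levels were measured by RNA sequencing in strain WX1 of Chryseobacterium, a genus of Gram-negative bacteria of the phylum Bacteroidota. The series concerns the breakdown of doxycycline by this strain. Doxycycline is a tetracycline antibiotic, and tetracyclines bind the small ribosomal subunit and block the entry of aminoacyl-tRNA. Cultures without doxycycline (control, n = 3) were compared with cultures given 50 mg/L doxycycline (n = 3). The deposited table listed 5194 features in TPM (a length-scaled share of transcripts with a fixed total), of which 4812 were reference genes, 213 were additional predicted genes and 169 were sRNAs. TPM sum to the same total in every library, so the sequencing depth of each library is unknown. The genome build and the positions of the genes were not given in the sources used here, and genes are named by the identifiers of the table.

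The comparison asks which transcripts of WX1 differ in abundance between cultures with and without doxycycline. A naming rule fixed beforehand picked 46 features, and the rankings here are among those above 0 TPM in all libraries. Their largest rises were in a block of neighbouring genes that includes an RNA ligase of the Rnl2 family. Next among these features were prfH and the efflux channel gene oprM. The deepest falls among these features were in a siderophore gene cluster, where siderophores are secreted compounds that bind iron. Relative to the typical gene, 24 of 42 ATP synthase and respiratory chain genes rose, whereas 14 of 19 chaperone and protease genes and 12 of 24 genes of the tricarboxylic acid cycle fell. As TPM, 6 of these 24 cycle genes were higher and 4 lower, so these counts depended on the scaling. The median log2 change of that list was below 0 on both scales, at -0.15 as TPM and -1.10 relative to the typical gene. On the TPM scale 2418 of 4955 tested genes were higher with doxycycline and 236 were lower (limma, Benjamini-Hochberg adjusted p under 0.05). That scale raised the median gene by 0.89 on the log2 scale. With libraries scaled by the median of ratios, so that the typical gene is set near no change, the median was -0.06, and 1066 genes were higher and 833 lower. All 1066 were among the 2418, and all 236 were among the 833. Of the genes called on both scales, 0 had opposite signs. Changes below are relative to the typical gene unless TPM is named, and "rose" and "fell" refer to genes past the threshold on that scale. The relative counts became 1476 higher and 1470 lower without control replicate 2, and the TPM counts 2409 and 679.

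The share of TPM taken by reference genes was 54.5%, 50.0% and 51.6% in control replicates 1 to 3, and 63.4%, 78.3% and 82.9% in doxycycline replicates 1 to 3. The feature novel0111, a predicted gene for a hypothetical protein, took 21.8%, 21.8% and 18.7% of TPM in the control libraries. It took 10.1% in doxycycline replicate 1 and was listed at 0 in doxycycline replicates 2 and 3. The feature novel0043 took 0.997%, 1.98% and 1.25% in the control libraries and 3.48% in doxycycline replicate 1. It too was listed at 0 in doxycycline replicates 2 and 3. The authors' deposited table gives log2 fold changes of -3.01 for novel0111 and -0.84 for novel0043 (adjusted p = 0.32). Whether these values of 0 are failed estimates cannot be told without counts. The feature novel0097 took between 14.3% and 22.7% in all 6 libraries.

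**Figure D1:**
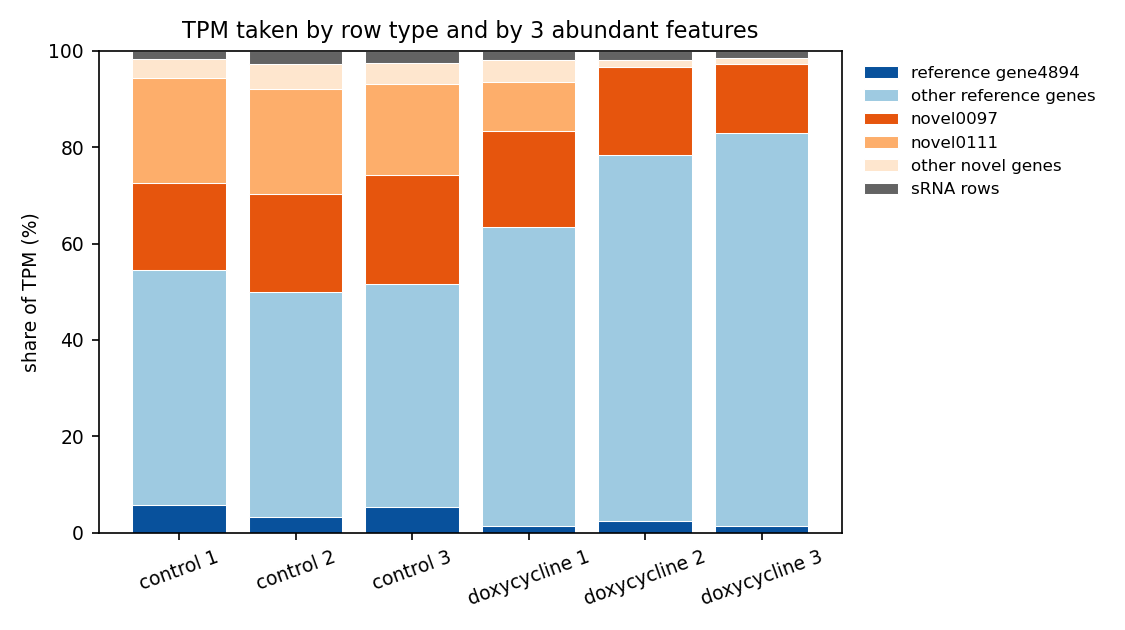
Share of TPM (%, stacked bars) taken in each of the 6 libraries by reference genes, additional predicted genes and sRNA rows, with gene4894, novel0097 and novel0111 drawn apart. Reference genes took 50.0% to 54.5% in the control libraries and 63.4% to 82.9% in the doxycycline libraries.

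The 5 rises that the naming rule selected, by TPM and among genes with an informative description, all lay in the block gene3972 to gene3977. The RNA ligase gene3973, of a family that seals nicks in RNA, rose from 12.2 ± 5.27 TPM in control cultures to 5366 ± 564 TPM with doxycycline (SD, n = 3 each), a relative log2 change of 7.76 ± 0.28 (SE, adjusted p = 4.14e-07). The exonuclease domain genes gene3976 and gene3977 rose by 7.71 and 6.91. The DinB family gene gene3972 rose by 7.39, and the metallophosphoesterase gene gene3975 by 7.11. The largest falls among named genes above 0 TPM in all libraries were in the siderophore cluster. The TonB-dependent siderophore receptor gene0727 went from 1296 ± 172 TPM to 4.25 ± 0.771 TPM, a relative log2 change of -8.86 ± 0.29 (adjusted p = 4.14e-07). Its neighbours gene0719, a TauD/TfdA dioxygenase that the table names asnO, and gene0720, an aminotransferase named ddc, had changes of -9.34 ± 0.55 and -8.77 ± 0.58. The rule also selected the additional features novel0085 and novel0090. The feature novel0085, described as cytochrome C551, had 6288, 12978 and 7750 TPM in control replicates 1 to 3 and 83.7 TPM in doxycycline replicate 1, and was listed at 0 in doxycycline replicates 2 and 3. Its adjusted p was 0.011 on the relative scale and 0.053 without control replicate 3. The feature novel0090 had 378, 156 and 186 TPM in the control libraries and was listed at 0 in all 3 doxycycline libraries.

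Neither tetX nor tetA, the 2 genes on the tetracycline resistance list, passed the test relative to the typical gene. The gene tetX (gene3750) encodes Tet(X), a monooxygenase that inactivates tetracyclines. It was at 354 ± 15.0 TPM in control cultures and 511 ± 105 TPM with doxycycline (SD, n = 3 each). Its log2 change was 0.50 ± 0.25 on the TPM scale (SE, adjusted p = 0.089) and -0.52 ± 0.31 relative to the typical gene (adjusted p = 0.23), so its sign depended on the scaling. With upper-quartile factors tetX was lower at -0.59 (adjusted p = 0.029), and with factors from genes of at least 100 TPM at -0.48 (adjusted p = 0.037). The TPM value was 0.69 with an adjusted p of 0.0090 when doxycycline replicate 1 was left out. The transporter gene tetA (gene0065) had 36.7 ± 9.80 and 87.0 ± 13.4 TPM. Its change was 1.25 on the TPM scale (adjusted p = 0.00029) and 0.24 relative to the typical gene (adjusted p = 0.45). Adjusted over the list alone, 0 of the 2 passed on the relative scale and tetA passed on the TPM scale.

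Among 77 multidrug efflux genes, 20 rose, 6 fell and 51 did not pass (19 and 6 adjusted over the list alone). As TPM, 30 were higher and 2 lower. The outer membrane channel gene oprM (gene3158), a TolC family member of RND pumps, rose by 5.13 ± 0.28 (adjusted p = 4.1e-06), from 7.64 ± 4.11 to 534 ± 121 TPM. The MATE family transporter gene gene0724, which is numbered within the siderophore cluster, had a change of -5.82 ± 0.28. Of 26 other antibiotic resistance genes, 8 rose, 3 fell and 15 did not pass, with equal counts adjusted over the list alone, and 13 were higher and 0 lower on the TPM scale. The regulator gene blaI (gene1050), of a family that represses beta-lactamase genes, rose by 3.30 ± 0.28, and gene3758, named lnuB_F and described as an aminoglycoside 6-adenylyltransferase, rose by 2.72 ± 0.55. Efflux counts were 24 higher and 27 lower without control replicate 2, and those of the other resistance genes 11 and 5. The other resistance counts were 7 and 1 without control replicate 1, and 5 and 1 without doxycycline replicate 2 or 3.

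Ribosomal protein genes moved both ways relative to the typical gene. Of 21 small subunit genes 3 rose and 4 fell, and of 33 large subunit genes 3 rose and 4 fell. Adjusted over the list alone these were 3 and 4, and 3 and 3. In TPM, 12 and 21 were higher and 1 of each list was lower. The neighbouring genes rplI (gene0965, protein L9) and rpsR (gene0964, protein S18) rose by 1.90 ± 0.33 and 1.27 ± 0.30. The genes rplS (gene4803, protein L19) and rpsT (gene3463, protein S20) had changes of -1.70 ± 0.32 and -1.94 ± 0.30. These small counts depended on single libraries. In the large list 1 gene was higher without control replicate 1 or 3 or doxycycline replicate 1, 2 without doxycycline replicate 2, and 6 without control replicate 2. In the small list 1 gene was higher when any one library other than control replicate 2 was left out, 1 was lower without doxycycline replicate 2, and 2 were lower without control replicate 1 or doxycycline replicate 3. The large list had 2 lower genes without doxycycline replicate 2.

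Of 21 translation factor genes, 3 rose and 4 fell, with equal counts adjusted over the list alone, while 12 were higher and 0 lower on the TPM scale. The gene prfH (gene2800), a release factor homologue, rose by 5.79 ± 0.30 (adjusted p = 3e-06), from 11.6 ± 6.93 to 1188 ± 95.2 TPM. The gene named fusA with the number gene3993, described as elongation factor EF-G, the translocase of the ribosome, rose by 4.19 ± 0.54 (adjusted p = 0.0015). This gene was low in control cultures, at 6.94 ± 4.86 TPM, and had 225 ± 63.1 TPM with doxycycline. The count higher was 5 without control replicate 2, and the count lower was 2 without doxycycline replicate 3. Of 24 aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 1 rose and 12 fell, also when adjusted over the list alone. As TPM, 11 were higher and 0 lower, so the direction of this list turned with the scaling. The gene that rose was cysS (gene3601), with a change of 0.75 ± 0.24 (adjusted p = 0.034), a call kept when control replicate 2 was left out and lost when any other library was. The gene trpS (gene2710) was at 0.48 relative to the typical gene (adjusted p = 0.10) and 1.48 on the TPM scale. The count of lower genes was 7 without control replicate 1, and 5 without doxycycline replicate 2 or 3. The count of higher genes was 4 without control replicate 2 and 0 when any other library was left out.

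Chaperone and protease genes were lower as a list with a preset correlation (camera on the relative scale, adjusted p = 0.00062), but not with an estimated correlation (adjusted p = 0.92). Of 19 genes, 14 fell, 1 rose and 4 did not pass, also when adjusted over the list alone, and on the TPM scale 10 were lower and 4 higher. The small heat shock gene gene0133, of the Hsp20 family that binds unfolded proteins, went from 4435 ± 953 to 890 ± 285 TPM, a change of -3.36 ± 0.42 (adjusted p = 0.00034). The chaperonin family feature novel0108 had 1.14 ± 0.51 relative to the typical gene (adjusted p = 0.12) and 2.11 on the TPM scale. The count of higher genes was 3 without control replicate 2. Of 47 oxidative stress genes 11 rose and 17 fell (12 and 17 adjusted over the list alone), against 23 higher and 3 lower on the TPM scale. The organic hydroperoxide resistance gene osmC (gene4853) rose by 3.92 ± 0.29 (adjusted p = 2e-05), and the thioredoxin family gene trxA (gene0284) had a change of -1.90 ± 0.33 (adjusted p = 0.0019). The oxidative stress count higher was 7 without doxycycline replicate 1 or 3 and 6 without doxycycline replicate 2.

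ATP synthase and respiratory chain genes were higher as a list with a preset correlation (camera on the relative scale, adjusted p = 0.0013), but not with an estimated correlation (adjusted p = 0.92). Of 42 genes, 24 rose, 5 fell and 13 did not pass (26 and 7 adjusted over the list alone), and on the TPM scale 31 were higher and 2 lower. The oxidase gene ccoNO (gene2297), for a cbb3-type terminal oxidase, went from 5666 ± 1385 to 276 ± 178 TPM, a change of -5.56 ± 0.57 (adjusted p = 0.00016). The feature novel0170, described as part of complex I subunit J, had 8.81 TPM in control replicate 1, was listed at 0 in control replicates 2 and 3, and had 312.6, 256.4 and 335.1 TPM in the doxycycline libraries. The count lower was 3 without doxycycline replicate 1 or 3. Of 24 genes of the tricarboxylic acid cycle and pyruvate oxidation, 12 fell, 1 rose and 11 did not pass (12 and 2 adjusted over the list alone). In TPM, 6 were higher and 4 lower. The malate synthase gene aceB (gene2135), an enzyme of the glyoxylate shunt, had a change of -3.25 ± 0.35 (adjusted p = 0.00015), from 1235 ± 137 to 276 ± 98.8 TPM. The fumarate hydratase gene fumA (gene2815) was at 2.11 ± 0.66 relative to the typical gene (adjusted p = 0.052) and 3.02 on the TPM scale (adjusted p = 0.039). In this list 2 genes were higher without control replicate 2 or 3.

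**Figure D2:**
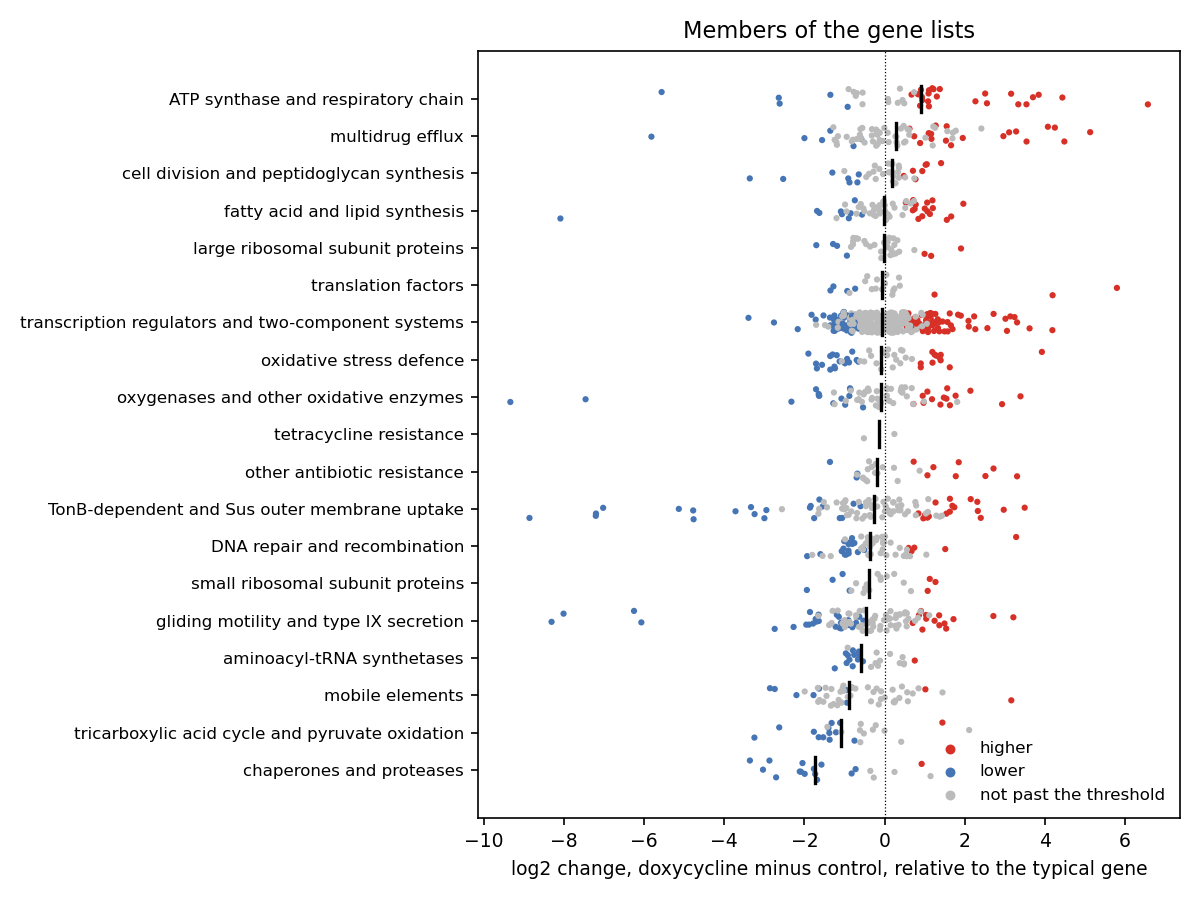
Log2 change of each tested member (points) of the 19 gene lists, doxycycline minus control relative to the typical gene, with the list median as a black bar; red points were higher, blue points lower and grey points not past the threshold. The chaperone list has 14 of 19 members lower, and the respiratory list 24 of 42 members higher.

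Outer membrane uptake genes of the TonB-dependent and Sus type, which import iron complexes, glycans and other large substrates, moved both ways. Of 100 genes, 17 rose and 21 fell, also when adjusted over the list alone, and on the TPM scale 37 were higher and 10 lower. The TonB-dependent receptor gene gene0055 rose by 3.49 ± 0.27, from 30.8 ± 2.37 to 719 ± 59.7 TPM. These counts were 25 and 46 without control replicate 2. Of 100 gliding and type IX secretion genes, 14 rose and 28 fell (15 and 28 adjusted over the list alone), against 43 higher and 9 lower on the TPM scale. The PorT family gene gene0648 rose by 3.21 ± 0.27, and gene4841 had a change of -8.31 ± 0.85. The product of gene4841 carries a type IX sorting domain, which marks cargo and not the secretion machinery. These counts were 22 and 40 without control replicate 2, and 9 were higher without doxycycline replicate 2.

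Of 70 oxygenase and other oxidative enzyme genes 14 rose and 14 fell, also when adjusted over the list alone, and on the TPM scale 33 were higher and 5 lower. The gene paaD (gene3671), for a subunit of the phenylacetyl-CoA oxygenase, rose by 3.39 ± 0.22 (adjusted p = 1.25e-05). Without doxycycline replicate 1, 2 or 3 the oxygenases lower numbered 8, 7 and 8, and without doxycycline replicate 3 those higher numbered 9. Of 58 fatty acid and lipid synthesis genes 16 rose and 9 fell, also when adjusted over the list alone, with 36 higher and 3 lower on the TPM scale. The members with the largest changes were the 3-oxoacyl-ACP synthase gene gene2681, at 1.96 ± 0.44, and the acyl carrier protein gene gene0725, at -8.09 ± 0.61. The latter is numbered within the siderophore cluster. The call of gene2681 was lost without doxycycline replicate 2 (adjusted p = 0.074) or 3 (adjusted p = 0.052). Of 37 cell division and peptidoglycan genes 7 rose and 7 fell, also when adjusted over the list alone, and 28 were higher and 2 lower on the TPM scale. The gene mrdA (gene3237), for a peptidoglycan synthesis enzyme, rose by 1.41 ± 0.19, and the murein L,D-transpeptidase gene gene3284 had a change of -3.36 ± 0.36. In this list 14 were higher without control replicate 2, and 4 were lower without doxycycline replicate 2.

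Of 60 DNA repair genes 5 rose and 16 fell (5 and 13 adjusted over the list alone), against 22 higher and 1 lower on the TPM scale. The gene gene2960, described as a DNA repair ATPase, rose by 3.28 ± 0.19, and ssb (gene1008), for the single-stranded DNA-binding protein, had a change of -1.93 ± 0.26. Of 50 mobile element genes 2 rose and 8 fell (2 and 6 adjusted over the list alone), with 12 higher and 4 lower on the TPM scale. The phage holin gene gene1548 rose by 3.16 ± 0.25, and the phage baseplate feature novel0005 had a change of -2.74 ± 0.66, a call lost without doxycycline replicate 2 (adjusted p = 0.078) or 3 (adjusted p = 0.068). Of 313 genes for transcription regulators and signalling proteins 64 rose and 48 fell (61 and 46 adjusted over the list alone), with 146 higher and 4 lower on the TPM scale. The helix-turn-helix features novel0035 and gene2813 had changes of 4.18 ± 0.42 and -3.40 ± 0.39. DNA repair counts were 10 and 22 without control replicate 2, the mobile element counts 7 and 30, and 76 regulators were lower. Without doxycycline replicate 2 or 3 the lower counts were 8 and 7 for DNA repair, 5 and 5 for mobile elements, and 23 and 26 for regulators. Without control replicate 3, 1 mobile element was higher.

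**Figure D3:**
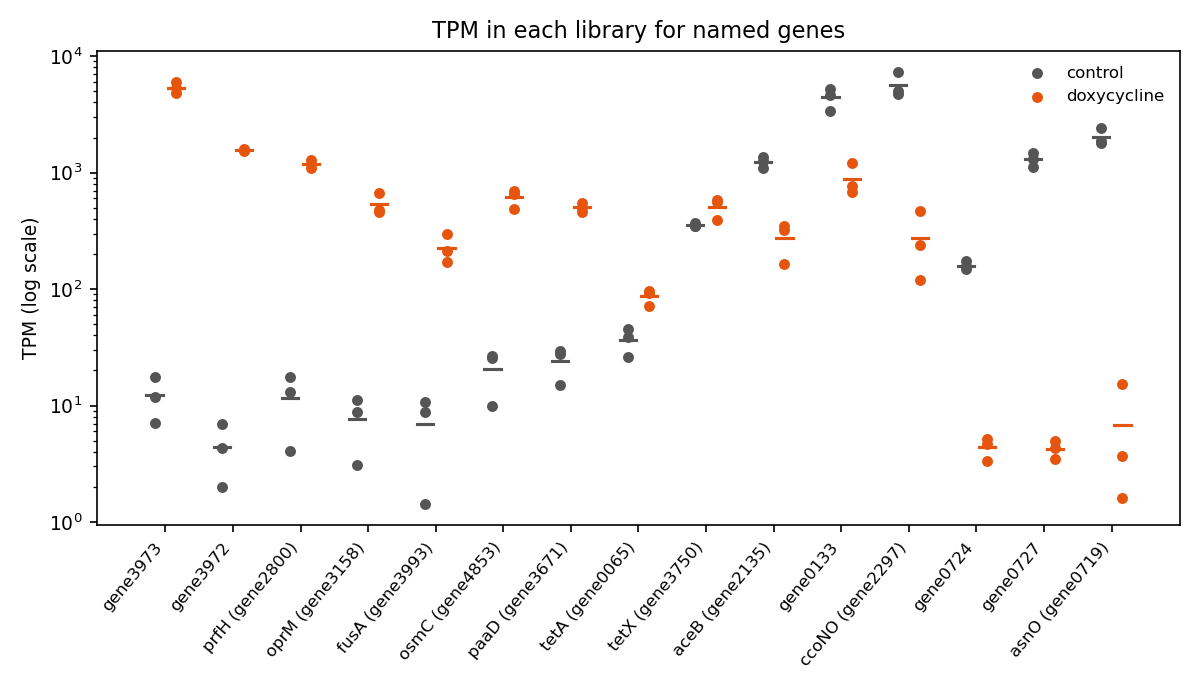
TPM (log axis) of named genes in each library, with 3 control points and 3 doxycycline points per gene and a bar at each group mean. The RNA ligase gene3973 stands at 12.2 TPM in control and 5366 TPM in doxycycline cultures, the siderophore receptor gene0727 at 1296 and 4.25 TPM.

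Of the 18 lists with at least 5 tested members, 5 differed from the other genes by camera with a preset correlation of 0.01 on the TPM scale, and 3 of these did so relative to the typical gene too. The chaperone list was lower (adjusted p = 7.58e-07 on the TPM scale and 0.00062 on the relative scale). The respiratory list was higher (0.0017 and 0.0013), and the tricarboxylic acid cycle list was lower (0.0064 and 0.0012). The lists of TonB-dependent uptake (0.013) and mobile elements (0.0040) were lower on the TPM scale, with adjusted p of 0.52 and 0.12 on the relative scale. With an estimated correlation the adjusted p was 0.97 on the TPM scale and 0.92 on the relative scale for each of the 5 lists, so that 0 calls held on either scale. Each of the 18 lists had these same values, so this setting could not tell the lists apart. With the preset correlation, 4 of the 10 splits of the 6 libraries into 3 and 3 gave at least 5 lists. Splits that mixed the groups gave 2 to 6. A call with the preset correlation therefore does not by itself show a link with doxycycline. On the TPM scale, only the chaperone and respiratory lists passed without control replicate 3, and the lists of the tricarboxylic acid cycle and mobile elements were lost without doxycycline replicate 2.

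The authors' deposited table marks 1325 features as significant, 722 of them higher and 603 lower with doxycycline. In that table tetX has a log2 fold change of -0.55 with an adjusted p of 0.14, and tetA 0.32 with an adjusted p of 0.37. All 1899 genes called relative to the typical gene have the same sign in the authors' deposited table, and 1251 of them are marked significant there. Among the rows marked there, the smallest absolute log2 fold change is 1.0002 and the largest adjusted p is 0.009998. The 1899 genes were called at an adjusted p under 0.05 with no minimum change. A called gene left unmarked there is therefore not by itself a disagreement. The labels do not say that replicates of a group came from separate cultures. The p-values therefore set the group difference against a spread between these samples that may be technical.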

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

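The use of RLE factors and an estimated correlation together, the scalings by reference genes, by genes of at least 100 TPM and without features of at least 10000 TPM, and all alternatives on the relative scale, were chosen after the data were seen. On the TPM scale, 2418 genes were higher and 236 lower. The counts were 1066 and 833 with RLE factors, 1015 and 1041 with upper-quartile factors, 1063 and 845 with factors from genes of at least 100 TPM, and 1287 and 634 without features of at least 10000 TPM. With reference genes only they were 1738 and 413. The split thus follows the scaling. Pseudocounts of 0.1 and 5, the filters, a threshold of 0.01, a minimum log2 change of 1 and the replicate block kept the TPM counts within 1.5 times. With one library left out, changed genes ranged from 2182 to 3088, higher genes from 1981 to 2528 and lower genes from 199 to 679. Relative to the typical gene, 1899 genes changed (1066 higher, 833 lower). An adjusted p under 0.01 gave 1220 changed and 486 lower genes, and a minimum log2 change of 1 gave 536 lower genes. With one library left out, changed genes ranged from 1396 to 2946, higher genes from 821 to 1476 and lower genes from 572 to 1470. The upper ends are those without control replicate 2. The cause was not tested.

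Of 5 lists called on the TPM scale, 0 held with an estimated correlation, on the TPM scale or with RLE factors. The counts were 3 with RLE factors, 3 with factors from genes of at least 100 TPM and 2 with the replicate block, which kept the chaperone and respiratory lists and lost the tricarboxylic acid cycle (adjusted p = 0.12), TonB-dependent uptake (0.078) and mobile elements (0.12). With one library left out they ranged from 2 to 6. The gliding and type IX secretion list (adjusted p = 0.089) gained a call with reference genes only (0.041), without control replicate 1 (0.041) and without doxycycline replicate 3 (0.035), and had 0.33 with the patterns as first written. The fry test, which asks whether a list moves at all, was run on the TPM scale only. It called 13 lists by direction and 18 in either direction. All directional calls but that of the chaperone list were higher, on a scale that raised the median gene by 0.89. They include the synthetase list (adjusted p = 0.032), where 12 of 24 genes fell relative to the typical gene. These calls cannot be told apart from that shift. For the lists of the tricarboxylic acid cycle, TonB-dependent uptake and mobile elements fry pointed up without a call, where camera called them lower. For lists that did not pass, camera's direction turned in several settings. The values given here are list median minus median of all genes, and their sign need not match camera's direction. For RLE, upper-quartile and 100 TPM factors these values were -0.325, -0.324 and -0.310 for the small ribosomal subunit, with -0.319 for reference genes only. Camera pointed down there, and up on the TPM scale, although the value was -0.253 on that scale too. With the same 3 factors the values were 0.0434, 0.0438 and 0.0578 for the large subunit, where camera's direction was down although the median was above 0. For translation factors they were -0.00575, -0.00475 and 0.00821, and for regulators -0.0063 and 0.000424 with RLE and upper-quartile factors. Camera pointed down in each of these settings, also where the value lay above 0. The synthetase list, where camera pointed up on the TPM scale although its median lay below that of all genes, turned down with RLE (-0.52), upper-quartile (-0.52, adjusted p = 0.036) and 100 TPM factors (-0.51), reference genes only (-0.49), the replicate block (-0.47) and the patterns as first written (-0.32). With one library left out its values were -0.52 to -0.36, those of multidrug efflux -0.36 to 0.48 and those of oxidative stress -0.106 to -0.00937. The replicate block gave -0.0751 for oxidative stress, where camera pointed up.

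Among named genes, only tetX changed sign, to -0.52 (RLE), -0.59 (upper quartile, adjusted p = 0.029), -0.48 (100 TPM factors, adjusted p = 0.037), -0.0109 (reference genes only) and -0.29 (without features of at least 10000 TPM). With RLE factors 4 of 46 lost their TPM call (fumA, novel0108, trpS and tetA). With one library left out, lnuB_F, fumA, rplS, trxA, ssb, novel0005 and novel0085 lost their TPM call at least once, 4 of them without doxycycline replicate 2. Whether replicate numbers pair the samples is not known. Deviations of same-numbered libraries correlated at 0.22, 0.12 and -0.15, and those of differently numbered libraries at -0.26 to 0.21. With 3 libraries per group these values cannot settle it. The replicate block gave 2465 changed genes on the TPM scale and 1882 relative to the typical gene, and took the call of novel0085. The planned count tests and voom were not run, as the table holds no counts. Library totals alone are the TPM scale itself. The depth of the libraries is unknown, so its limits could not be computed.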

Other observations

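The tests in this part were chosen after the results were seen, except those on RNA from the doxycycline cultures and on an even background, and the splits of the samples for relative gene counts and for gene lists. Genes named here were chosen after their values were seen. Of 25 genes for iron and haem acquisition, gathered from names and descriptions, 16 fell and 2 rose, with a median relative log2 change of -3.92. They include the siderophore biosynthesis gene gene0723 (-7.21), the haem uptake genes hmuT (gene4844, -6.21) and hmuU (gene4845, -5.39), and the ferrous iron transport genes feoA (gene3000, -3.92) and feoB (gene2999, -2.97). The list was lower than other genes by camera with a preset correlation (adjusted p = 1.29e-07), and its adjusted p was 0.10 with an estimated correlation. The list was gathered after these falls were seen, so neither test is independent of it, and a coordinated fall of iron uptake was left undecided. All 7 R-body genes fell (median -3.83), as did 8 of 9 arginine biosynthesis genes (median -2.82). Of 14 phenylacetate degradation genes 8 rose and 1 fell, and of 5 genes for RNA ligation and rescue 3 rose, among them rtcB (gene2802, 5.65). The adjusted p of these 4 lists with an estimated correlation was 0.14, 0.14, 0.10 and 0.10.

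The succinate dehydrogenase genes sdhC (gene1907) and sdhC (gene2504) rose by 4.43 and 2.26, while novel0096, described as part of a flavoprotein subunit of this family, was at -2.62. The cbb3 oxidase genes ccoNO (gene2758) and ccoQ (gene2759) rose by 2.55 and 3.33, whereas the second ccoNO copy (gene2297) was at -5.56. Among chaperones, htpG (gene2278), clpB (gene3662), dnaK (gene1932) and groEL (gene2328) had changes of -3.03, -2.71, -2.05 and -1.68. Changes often covered runs of consecutively numbered genes. There were 34 runs of at least 5 genes with a relative log2 change of at least 1 in one direction, 22 higher and 12 lower. In 1000 shuffled gene orders the highest number was 3. This is consistent with transcription in blocks of neighbouring genes, on the assumption that the numbers follow gene order. The run from gene3970 to gene3978 had a median of 7.11, that from gene2797 to gene2803, with prfH and rtcB, 5.65, and that from gene0719 to gene0728 -7.68.

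Most genes were higher on the TPM scale with doxycycline, with a median of 0.89. Without control replicate 2 the median was 0.66, which argues against that library as the whole cause. After removal of the 11 features of at least 10000 TPM it was 0.15, and from -0.07 to 0.30 with one library left out as well. A few features taking most of the TPM could therefore account for much of the shift, although with all libraries the median was not within 0.1 of 0. A change of total mRNA with doxycycline stays open, since TPM cannot show it.

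Weakly expressed genes were lower in control replicate 2 than in control replicates 1 and 3. Control replicate 2 had 4356 features of at least 1 TPM, and the other libraries had 4880 to 4991. Among the 374 reference genes under 0.5 TPM in control replicate 2, the medians were 6.49, 0.235 and 5.22 TPM in control replicates 1 to 3. In doxycycline replicates 1 to 3 the medians of these genes were 3.27, 2.58 and 2.645 TPM. Among the 142 most strongly expressed genes of control replicate 2, the medians in control replicates 1 to 3 were 948, 929 and 863 TPM. These genes were chosen by their values in control replicate 2, which by itself favours such a pattern. Genes were therefore also chosen by doxycycline TPM. The ratio of the median TPM of control replicates 1 and 3 to that of control replicate 2 was 2.60 times larger in the 2406 weaker reference genes than in the 1203 strongest (bootstrap range 2.42 to 2.82), which argues against one scaling factor per library. In means over 54 genes under 1 TPM with doxycycline, set against 598 genes of a higher range, the same quantity was 0.105 with gene4291, which had 1119 TPM in control replicate 2 alone, and 11.3 without it. These genes lie near 0 and the depth is unknown, so a difference in depth stays open. Among the 572 reference genes under 1 TPM in control replicate 2, the fold between the top and bottom 10% by doxycycline TPM was 99.2 in the doxycycline libraries but 2.82 in control replicates 1 and 3, which argues against RNA from the doxycycline cultures. An even background of reads, such as from genomic DNA, could add a constant. Among the same 572 genes, the upper quartile in control replicates 1 and 3 was 2.22 times the lower quartile. That lay between the bounds of 2 and 3 set for it, so such a background stays open. Low transcription of these genes stays open too. The relative scale divides each library by one factor, 0.877, 0.483 and 0.814 for control replicates 1 to 3. The medians of the 1203 strongest genes were closer, at 110.72, 97.8 and 104.33 TPM. Those of the 2406 weaker genes were 12.77, 4.16 and 11.205 TPM. After division, control replicate 2 was therefore the highest control for the strongest genes and the lowest for the weaker ones. Whether this spread lowered the number of calls was not tested.

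The log2 fold change of the authors' deposited table lay below the relative change in rpm genes. The difference between that table's log2 fold change and the relative change had a median of -0.29 over 10 rpm genes, which encode the smaller proteins of the large subunit, and -0.04 over 23 rpl genes. The difference of -0.25 had a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give, across genes that are not independent replicates. Feature lengths are not given, so whether effective length plays a part was left open. The feature gene4291 was listed at 0 TPM in 5 of 6 libraries, while the authors' deposited table gives it a log2 fold change of -0.93. A change in these genes themselves was not tested apart from this.

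With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 2654 changed genes on the TPM scale and the highest other split 1. Relative to the typical gene the numbers were 1899 and 2. For gene lists by camera with the preset correlation, the real split gave 5 lists and the highest other split 6, and 4 of the 10 splits gave at least 5.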
